A study of Mus musculus with 2 samples.

How the data were processed

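Gene expression was measured by RNA sequencing in 2 samples of mouse 46C embryonic stem cells, 1 with a hairpin against linc1557 and 1 with a control hairpin. Per the labels' protocols, RNA was taken with Trizol and libraries were made with an Illumina TruSeq RNA kit. The deposited values are raw read counts per gene for each sample, with a gene length column. Per the submitters' processing notes, Trim Galore, HISAT2, featureCounts and DESeq were used, with builds mm10 and GRCm38. Their versions, the annotation release, the strand setting and the treatment of reads in overlapping genes are not given in the sources used here. The kit's strand protocol is not stated either, so reads of a gene and an antisense or overlapping partner cannot be told apart. Rn7s2 and the overlapping Gm47305 had nearly equal counts, 222986 and 222014 in the knockdown library, as when a read is counted for both. Genes with near-identical copies can share or lose reads in such counting, and ratios of Ifit3, Ifit3b, Tuba3a, Zscan4c, Zscan4f, histone and ribosomal protein genes are uncertain for that reason.

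The table held 46983 genes by Ensembl identifier, of which 18951 had 0 counts in both libraries. Symbols, classes and GRCm38 coordinates were taken from the GENCODE annotation of that build given for this work. It matched 46488 identifiers and left 495 unmatched, which took 0.119% (0.118 to 0.121) of the knockdown and 0.128% (0.126 to 0.129) of the control counts (95% Wilson intervals). Totals were 26693282 counts in the knockdown and 23146210 in the control library, and the entered genes had median counts of 336 and 325. Ribosomal RNA had been partly retained. Mitochondrial rRNA took 14.47% (14.45 to 14.48) of the knockdown and 12.56% (12.54 to 12.57) of the control counts, nuclear rRNA 6.56% (6.55 to 6.57) and 5.27% (5.26 to 5.28), and protein-coding genes 62.8% (62.78 to 62.81) and 66.6% (66.59 to 66.63). Duplicate reads cannot be told from separate molecules here, so all intervals and floors cover counting error only.

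From the counts, TMM factors were computed with edgeR 4.0.16 in R 4.3.3 (0.960 for the knockdown and 1.04 for the control library). Ratios, intervals and percentiles were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A gene entered when its TMM-normalised CPM, the count scaled to library size, reached 1 in either library. Ratios are knockdown over control without a pseudocount. A count of 0 was set to a floor of 3 counts, so that the ratio is a bound, and no ratio was given when both counts were at most 3. With 1 library per group no test across replicates could be made. A gene was called by size, when the ratio was at least 2-fold and its exact 95% Clopper-Pearson interval excluded 1.

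Before the data were examined, 27 gene lists were fixed, among them markers of feeder fibroblasts. Each list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, and stood apart below the 1st or above the 99th percentile. This was done for the 26 lists with at least 5 entered genes, and in the same way for chromosomes. Genes named in the text follow a rule fixed at the same time. They are the 12 highest and 12 lowest called genes by the nearer bound of their interval, leaving out predicted models, 12 pluripotency and LIF pathway genes whatever their value, and for each list up to 4 called members with the largest change, or up to 2 of the most abundant where none was called. The rule names 100 genes, some of which are not reported here.

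The calling rule was tested on simulated data, for the knockdown library against the control library, with 50 genes planted at each fold size. With counting noise only, it recovered 25 of 50 genes at 2-fold (50%) and all at 3-, 4- and 8-fold, and it called 24 of 15327 unchanged genes (0.157%). With an assumed CV of 0.2 it recovered 46%, 90%, 98% and 100% and called 539 of 15433 unchanged genes (3.49%). Of 200 unchanged lists of 20 genes, 7 (3.5%) stood apart with counting noise only and 3 (1.5%) with the assumed CV.

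Settings tried beside these were total-count scaling, DESeq2 1.42.0 size factors, no filter, a filter at 5 CPM, a prior count of 2, thinning of the deeper library, centring by expression level or gene length, fold thresholds of 1.5 and 4, and leaving out genes on more than 1 list. Nuclear protein-coding genes alone, chromosome 14 left out and centring in 10 bins of transcript GC content were added after seeing the data, as were windows of 10 Mb along each chromosome and 5 further gene groups, given among the closing observations. The target linc1557 was not matched to a row and is not reported.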

Results

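Transcripts were counted per gene in 2 RNA sequencing libraries made from total RNA of 46C cells, a mouse embryonic stem cell line that carries a green fluorescent protein reporter at the Sox1 locus. The cells grew on feeder cells in serum with leukaemia inhibitory factor (LIF), the cytokine that signals through Lifr, Il6st, Jak1 and Stat3 to sustain self-renewal. One library came from cells with a short hairpin RNA against the long noncoding RNA linc1557, the other from cells with a control hairpin. In both cases stably infected clones had been picked after puromycin selection. The knockdown library held 26693282 counts and the control library 23146210. The series title places linc1557 in the start of differentiation and in LIF/STAT3 signalling, so the comparison asks which genes of these programmes differed between the 2 libraries. There was 1 library per group and therefore no replicate check, no test and no p-value. A gene was called higher or lower when it differed by at least 2-fold and its 95% counting interval excluded 1. The intervals in brackets cover counting error only and say nothing of the spread between cultures or clones.

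The target came first in the design, but no gene name in the table or in the reference annotation matched linc1557, so its level was not analysed here. The labels therefore stand without a check of the knockdown, and the libraries are named as labelled.

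Of the genes that mark formative pluripotency, the primitive streak and mesoderm, and the endoderm, 10 of 19, 8 of 13 and 10 of 16 were lower in the knockdown library, and the other members were not called or, for 1, 2 and 1 genes, higher. Markers of feeder fibroblasts were lower as well (19 of 30), with a median log2 ratio of -1.28. The formative, streak and endoderm lists had medians of -1.47, -2.24 and -1.25. Pou5f1, Sox2 and Nanog differed by less than 2-fold. Higher were 16 of 24 interferon response genes, with none lower, and 9 of 17 germline genes, with 3 lower. Of 15850 genes that entered, 742 (4.68%) were higher and 1503 (9.48%) were lower in the knockdown library, and 13605 (85.8%) were not called. At least 8-fold differences were found for 41 genes on the higher side and 146 on the lower side. The median log2 ratio of all entered genes was 0.02, with quartiles of -0.35 and 0.33. Scaling by total counts alone shifted that median by -0.12, so each ratio is relative to the TMM scaling. Libraries were also simulated with an assumed CV of 0.2, drawn for each gene separately in each library. There 539 of 15433 unchanged genes (3.49%) met the rule, a share that such variation alone would give. The true spread between cultures was not measured.

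**Figure D1:**
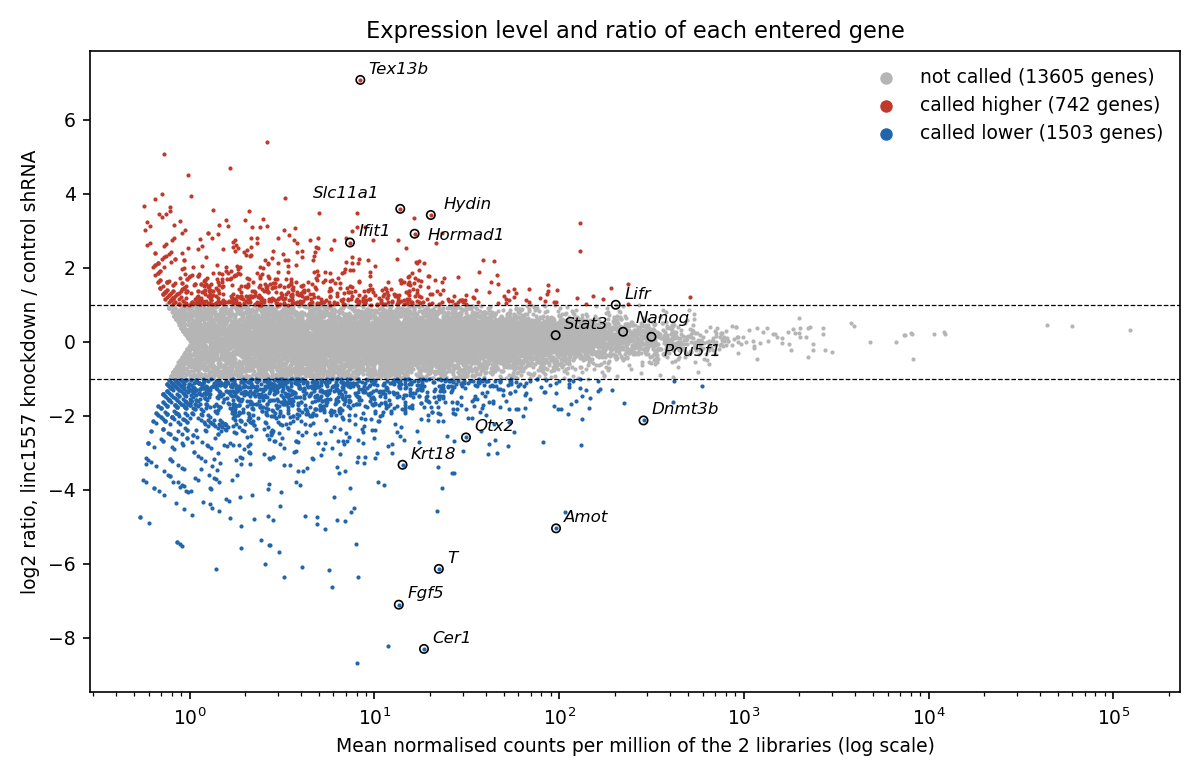
Each point is 1 of the 15850 entered genes, with the mean normalised CPM (counts scaled per library) of the 2 libraries on the horizontal log axis and the log2 ratio of knockdown to control on the vertical axis; dashed lines mark 2-fold, red points are the 742 genes called higher and blue points the 1503 called lower. Circled are named genes, among them Cer1 at -8.30, T at -6.14 and Tex13b, whose control count of 0 was set to 3 counts, at 7.08.

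Of the 12 lowest genes, T, Fgf8 and Gsc are on the streak list, Cer1 and Foxa2 on the endoderm list and Fgf5 on the formative list. Cer1, a secreted inhibitor of NODAL and BMP, had 3 counts in the knockdown and 892 in the control library, a 316-fold lower level (108 to 1535). Lhx1, a homeobox factor of the early mesendoderm, had 2 against 566 counts and was 301-fold lower (82.9 to 2489). Cyp26a1, which degrades retinoic acid, had 1 against 389 counts and was 413-fold lower (73.7 to 16366). Fgf5, the classical marker of the post-implantation epiblast, was 138-fold lower (58.8 to 426), and T (brachyury) was 70.5-fold lower (43.2 to 124), with 16 against 1062 counts. The WNT antagonist Dkk1 had 0 counts against 146 and was at least 51.7-fold lower, taken against a floor of 3 counts (interval from 41.5). The others among the 12 lowest were Car4 (82.2-fold), Foxa2 (99.5-fold), Amot (33.0-fold, from 145 against 4505 counts), Fgf8 (72.0-fold), Foxq1 (44.2-fold) and Gsc (68.0-fold).

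In GRCm38 coordinates, Cer1 (ENSMUSG00000038192) lies on chromosome 4 from 82881751 to 82885148. Lhx1 (ENSMUSG00000018698) lies on chromosome 11 from 84518284 to 84525535, Fgf5 (ENSMUSG00000029337) on chromosome 5 from 98254184 to 98277030, and T (ENSMUSG00000062327) on chromosome 17 from 8434423 to 8442496. Dnmt3b (ENSMUSG00000027478) lies on chromosome 2 from 153649450 to 153687730 and Lifr (ENSMUSG00000054263) on chromosome 15 from 7090614 to 7197489. Counts are per gene and do not separate exons or transcript forms.

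The list of primitive streak and mesoderm genes had 13 entered members, of which 8 were lower, 2 were higher and 3 were not called. Its median log2 ratio was -2.24, below all 10000 random lists of the same size and expression. Besides T, Fgf8 and Gsc, the streak-inducing ligand Wnt3 was 40.7-fold lower (13.6 to 200). The 2 higher members, named after their values were seen, were Mesp2 (log2 ratio 1.08) and Tbx6 (1.02). Of the 16 primitive and definitive endoderm genes, 10 were lower, 1 was higher and 5 were not called, with a median of -1.25, again below every random list. Sox17 was 81.8-fold lower (22.3 to 682) and Gata6 16.8-fold lower (8.58 to 37.4). The member on the higher side was Hnf4a (1.47), also named after its value was seen. Among 10 trophectoderm genes, 6 were lower and none was higher, with a median of -1.86 at percentile 0. Krt8 and Krt18, keratins of simple epithelia, had log2 ratios of -3.56 and -3.33, from 105 against 1163 and 66 against 623 counts, and Cdx2 and Krt7 were 16.5-fold and 13.8-fold lower from 2 against 31 and 5 against 65 counts. This list shares members with the ectoderm and streak lists, and without shared genes its percentile was 18.985, so it did not then stand apart.

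Formative and primed pluripotency genes were lower as a group, with 10 of 19 lower, 1 higher and 8 not called, and a median of -1.47 at percentile 0. Behind Fgf5 came Wnt8a at 21.6-fold (10.2 to 54.6), Sox3 at 13.8-fold (3.46 to 120, from 2 against 26 counts) and the kinase gene Pim2 at 7.76-fold (6.63 to 9.13). The member that was higher was Etv4, an ETS factor, at 2.50-fold (2.30 to 2.71). Core and naive pluripotency genes showed another picture. Of 26 entered members, 1 was higher, 1 was lower and 24 were not called, and the median of 0.25 lay at percentile 99.58. Pou5f1 had a log2 ratio of 0.13, Sox2 0.02, Nanog 0.27, Klf4 0.24, Esrrb 0.51 and Tfcp2l1 0.68, all under 2-fold. Tbx3, a factor downstream of LIF, was 2.20-fold higher (2.04 to 2.37), and Dppa3 was 3.91-fold lower (3.06 to 5.06). The percentile of this list fell short of 99 without genes shared between lists (92.385) and without chromosome 14 (98.535).

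The LIF pathway itself differed little at the level of its transcripts. Of 23 entered receptor and JAK-STAT components, 22 were not called, and the median log2 ratio of 0.01 lay at percentile 40.3. Lifr, the LIF receptor gene, was 2.00-fold apart with 6917 against 3259 counts (1.92 to 2.08). It fell just short of the call at a log2 ratio of 0.9983, and it passed with DESeq2 size factors (1.04) and after centring by gene length (1.03). Il6st, which encodes the shared receptor subunit gp130, had a log2 ratio of 0.54, Lif -0.12 with 87 against 89 counts, Jak1 -0.07 and Stat3 0.18. Socs3, the feedback inhibitor that STAT3 induces, stood at 0.66. Among 18 STAT3 target genes, only Gbx2 was called, 2.63-fold higher (2.30 to 3.00), and the list's median of 0.21 lay at percentile 93.9, within the range of random lists. Transcript counts carry no measure of STAT3 phosphorylation.

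**Figure D2:**
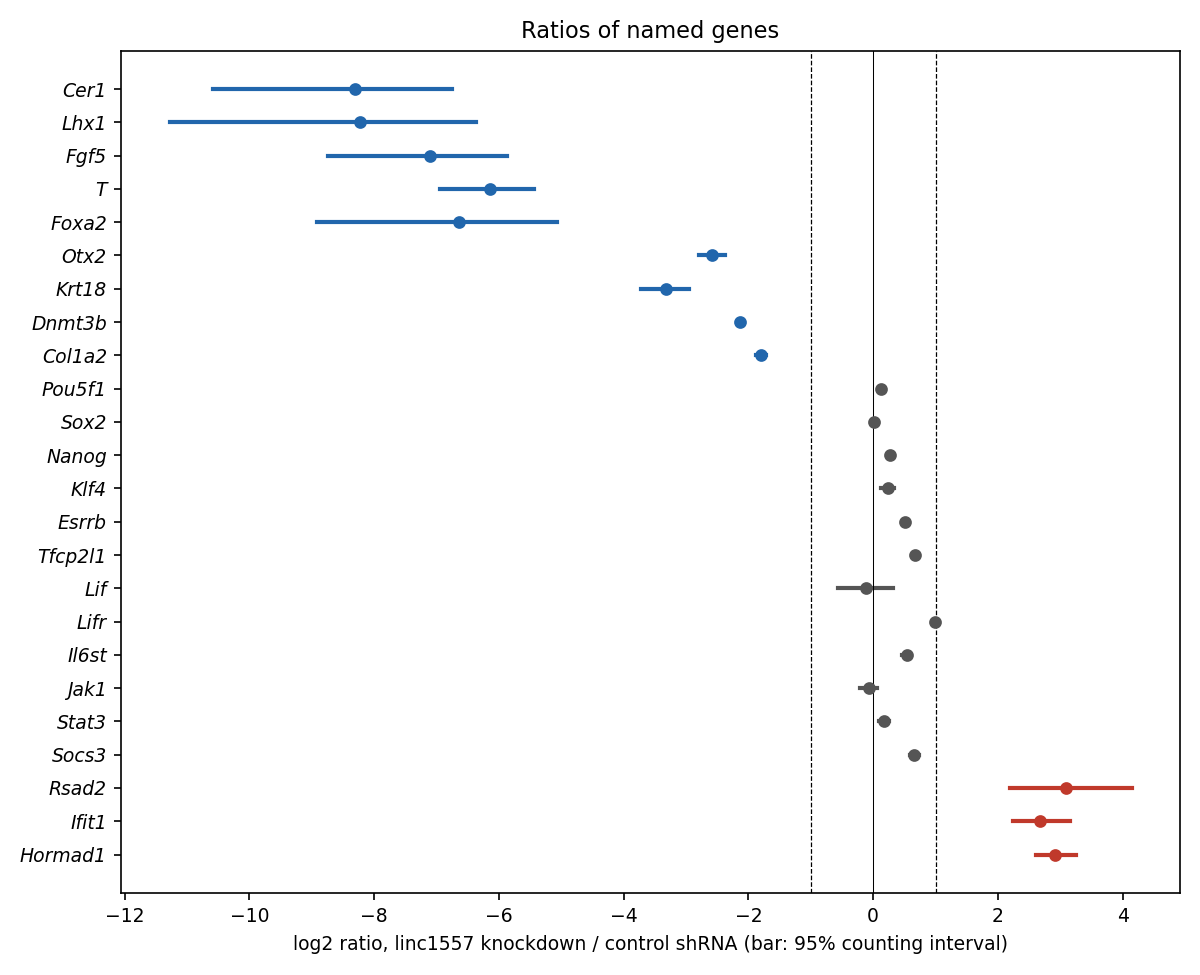
Points give the log2 ratio of knockdown to control for 24 named genes and bars the 95% counting interval, with dashed lines at 2-fold; red marks genes called higher, blue genes called lower and grey genes not called. The 12 pluripotency and LIF pathway genes from Pou5f1 to Socs3 lie between -0.12 and 1.00, while Cer1, Lhx1, Fgf5, T and Foxa2 lie at or below -6.14.

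Lists of signal-responsive genes hold partly the same genes. NODAL and BMP responsive genes had 5 of 15 lower and none higher, with a median of -0.72 at percentile 0.02. Lefty1, a NODAL antagonist and target, was 7.11-fold lower (6.33 to 8.0) and Msx1 20.7-fold (5.36 to 177, from 2 against 39 counts). WNT responsive genes had 7 of 15 lower and none higher, with a median of -0.69 at percentile 0.61, and Lgr5 was 47.3-fold lower (12.7 to 396, from 2 against 89 counts). That list no longer stood apart without genes held in common with other lists (percentile 6.52), with a filter of 5 CPM (1.355) or with nuclear protein-coding genes alone (2.09). FGF-ERK responsive genes went both ways, with 3 higher and 3 lower of 18 and a median of -0.03 at percentile 24.9. Dusp4 was 3.71-fold lower (3.19 to 4.32), Fos 3.38-fold lower (3.07 to 3.72) and Spry1 2.20-fold lower (1.81 to 2.67), whereas Etv4 was 2.50-fold higher (2.30 to 2.71). Without shared genes this list lay at percentile 0.45.

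Of 12 neural and ectoderm genes, 2 were higher and 3 lower, with a median of -0.19 at percentile 10.6. The lower members included the keratin genes Krt8 and Krt18, which are also on the trophectoderm list, and the higher ones were Gbx2 and Sox1. Without shared genes the list lay at percentile 26.3. Sox1, the neuroectoderm factor at whose locus 46C cells carry the reporter, was 7.66-fold higher (3.49 to 19.9) from 57 against 7 counts. Of 9 entered HOX genes, 6 were lower and none was higher, and the median of -1.22 lay at percentile 5.46. Their counts were small, as for Hoxa7 with 5 against 25 and Hoxb3 with 9 against 33. Hoxb2 and Hoxc9 had 7 against 27 and 9 against 26 counts and were no longer called after centring by expression level. With no filter on low counts the HOX list lay at percentile 0.06. Only 3 of the 2-cell-like genes entered, too few for a percentile, and Zscan4f and Zscan4c were 2.35-fold (1.54 to 3.66) and 2.33-fold (1.44 to 3.86) lower. These are near-identical copies, so the division of reads between them is uncertain.

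Markers of feeder fibroblasts were lower in the knockdown library, in the same direction as the streak, endoderm and formative lists. Of 30 markers, 19 were lower, none was higher and 11 were not called, and the median of -1.28 lay below every random list. Timp3 was 6.34-fold lower (5.62 to 7.17), Col6a3 5.41-fold (4.89 to 5.99), Col3a1 4.48-fold (4.07 to 4.95) and Col6a2 4.40-fold (3.78 to 5.14). Genes of actin and the serum response were lower as well, with 16 of 24 lower, none higher and a median of -1.17 at percentile 0. Acta2, smooth muscle actin, was 3.90-fold lower (3.66 to 4.17), Actg2 4.14-fold (2.88 to 6.08), Cnn1 3.93-fold (3.04 to 5.13) and Myl9 3.90-fold (3.38 to 4.52). Fibroblasts express most genes of this list, and Acta2 and Tagln are on both lists.

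Among the 12 highest genes, 5 had 0 control counts, and their ratios are taken against a floor of 3 counts, with the lower limit of the counting interval in brackets. Tex13b, a testis-expressed gene on chromosome X (140808307 to 140813433, ENSMUSG00000042386), had 430 counts against 0 and was at least 135-fold higher (109). Marco, a scavenger receptor of macrophages, had 135 against 0 and was at least 42.4-fold higher (34.0). Lcn2, Slc13a3 and Acod1 had 40, 35 and 30 counts against 0 and were at least 12.6-fold (9.74), 11.0-fold (8.47) and 9.41-fold (7.19) higher. Slc11a1 was 12.1-fold higher (9.06 to 16.4), Nos2, the inducible nitric oxide synthase, 25.7-fold (8.50 to 127, from 82 against 3 counts), and Hydin and Ttc29, genes of motile cilia, 10.7-fold (8.57 to 13.6) and 11.2-fold (7.78 to 16.6). Tuba3a was 7.66-fold higher (6.38 to 9.26) and Ifit3b 11.2-fold (7.06 to 18.6). Both have near-identical copies, so their ratios are uncertain.

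Interferon response genes were higher as a group. Of 24 entered members, 16 were higher, none was lower and 8 were not called, and the median of 1.36 lay above every random list. Ifi44 was 14.9-fold higher (7.88 to 31.6), the chemokine gene Cxcl10 11.6-fold (5.69 to 27.7), the antiviral gene Rsad2 8.56-fold (4.58 to 17.7) and Ifit3 8.53-fold (6.26 to 11.9). Germline genes followed, with 9 of 17 higher, 3 lower and a median of 1.02 above every random list. Hormad1, a meiotic chromosome axis gene, was 7.56-fold higher (6.09 to 9.48), the RNA-binding gene Dazl 3.28-fold (2.52 to 4.33), Brdt 3.27-fold (1.88 to 5.98) and Taf7l 3.22-fold (2.02 to 5.30). The lower members were Sycp3 (-1.60), Tdrd12 (-1.20) and Prdm1 (-1.16), named after their values were seen.

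Genes of the amino acid and unfolded protein response had a median of 0.51, above every random list, although 24 of 27 were not called. The 3 that were higher, Nupr1 (2.68-fold, 2.29 to 3.15), Chac1 (2.60-fold, 2.21 to 3.06) and Trib3 (2.23-fold, 1.94 to 2.57), are targets of the stress factor ATF4. The 15 mitochondrially encoded genes had a median of 0.36 at percentile 99.96, with none called. The mitochondrial rRNA genes mt-Rnr2 and mt-Rnr1 had log2 ratios of 0.33 and 0.27. After centring by GC content that list lay at percentile 97.935.

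Imprinted genes went both ways with wide differences. Of 33, 8 were lower, 2 were higher and 23 were not called, and the median of -0.32 lay at percentile 0.03. Magel2 was 31.5-fold lower (10.4 to 156, from 3 against 89 counts), the growth factor adaptor Grb10 6.94-fold lower (6.46 to 7.47) and the cell cycle inhibitor Cdkn1c 6.56-fold lower (5.40 to 8.04), whereas Plagl1 was 5.39-fold higher (3.77 to 7.90). The direction of this list depended on its weakly expressed members, since with a filter of 5 CPM its median was 0.24 at percentile 98.47. Without shared genes it lay at percentile 8.76.

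Among DNA methylation and Polycomb genes, 21 of 23 were not called and the median of -0.08 lay at percentile 6.76. The exceptions were the de novo methyltransferase gene Dnmt3b, 4.37-fold lower (4.19 to 4.56) with 2732 against 11239 counts, and Phf19, 2.13-fold lower (1.70 to 2.69). Cell cycle genes had 3 lower of 28, with a median of -0.03 at percentile 8.56: Cdkn1c, the cyclin gene Ccnd2 at 2.71-fold lower (2.48 to 2.96) and Cdkn2a at 2.04-fold lower (1.58 to 2.66), a call that DESeq2 size factors and centring by expression level or GC content ended. Of 20 p53 target genes, Gdf15 was called, 2.80-fold higher (1.90 to 4.20). Their median was -0.19 at percentile 1.04, a margin that several settings crossed. Glycolysis and hypoxia genes had 2 higher of 26, Pfkp at 2.32-fold (2.26 to 2.38) and Ndrg1 at 2.13-fold (1.89 to 2.40, no longer called when scaled by total counts), with a median of 0.15 at percentile 89.2. Of 24 cholesterol biosynthesis genes 23 were not called, and their median of 0.07 lay at percentile 51.3. Of 26 histone genes, Hist4h4 was 2.10-fold lower (1.99 to 2.22), with a list median of 0.02 at percentile 20.7. None of the 41 ribosomal protein genes was called, and their median of -0.01 lay at percentile 9.95. Rpl4 had a log2 ratio of 0.26 and Rpsa 0.11. Histone and ribosomal protein genes share sequence with copies and pseudogenes.

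Of 26 lists placed among random lists, 9 lay below the 1st percentile and 5 above the 99th. By chance 0.52 would lie there if the members of a list varied independently. Lists share genes and their members are regulated together, so the percentiles describe these 2 libraries.

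**Figure D3:**
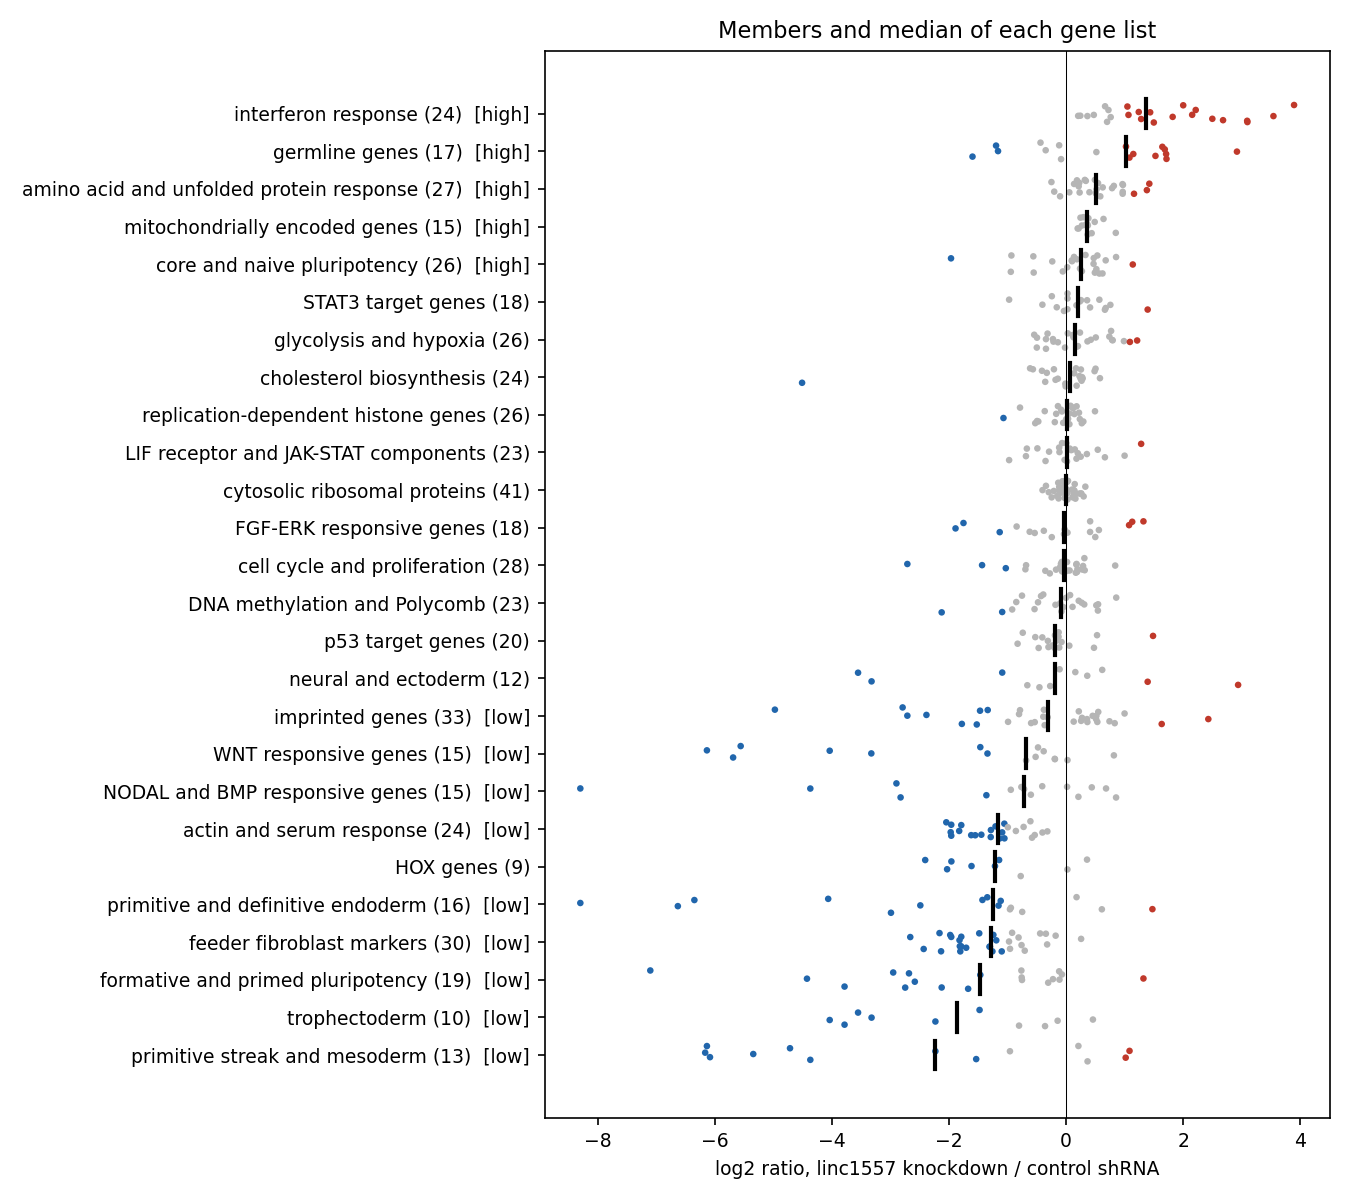
Each point is an entered member of a gene list, placed by its log2 ratio of knockdown to control, and black bars are list medians; red and blue points are genes called higher and lower, grey points were not called, numbers in brackets give entered members, and the words low and high mark lists below the 1st or above the 99th percentile of random lists. Medians run from -2.24 for primitive streak and mesoderm to 1.36 for interferon response.

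Chromosomes were compared because the cells had been picked as clones. Genes on chromosome 14 were lower as a group, with 103 lower and 15 higher of 537 and a median of -0.43, below every random list. Smaller medians below every random list were found for chromosome 16 (-0.18), chromosome 17 (-0.17) and chromosome 10 (-0.10), and chromosome 4 (-0.04) and chromosome 3 (-0.03) also lay below the 1st percentile. The medians of chromosomes 1, 2, 8, 9, 11, 12 and 13 lay above the 99th percentile, between 0.09 and 0.11. The 30 entered mitochondrial genes had a median of 0.46, also above it. Chromosomes 5, 6, 7, 15, 18, 19, X and Y lay within the range of random lists, with medians of 0.05, -0.00, 0.05, 0.07, 0.07, 0.04, -0.01 and -0.29. Most chromosomes thus lay outside that range, with medians as small as -0.03. A percentile alone therefore does not mark a gain or loss of a chromosome. Within chromosome 14, the 3 windows of 10 Mb from 50 to 80 Mb had medians of -0.69, -0.74 and -0.78, and 231 of their 251 genes lay below the genome-wide median. The windows from 0 to 10 Mb (-0.47, with 83.7% of genes below the genome-wide median) and from 40 to 50 Mb (-0.35, 77.5%) were low as well, and the other 4 windows with at least 20 genes had medians between -0.04 and 0.17. No gene named by the fixed rule lies in the windows from 50 to 80 Mb. The list members Gata4, Irf9, Piwil2 and Fdft1 do.

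**Figure D4:**
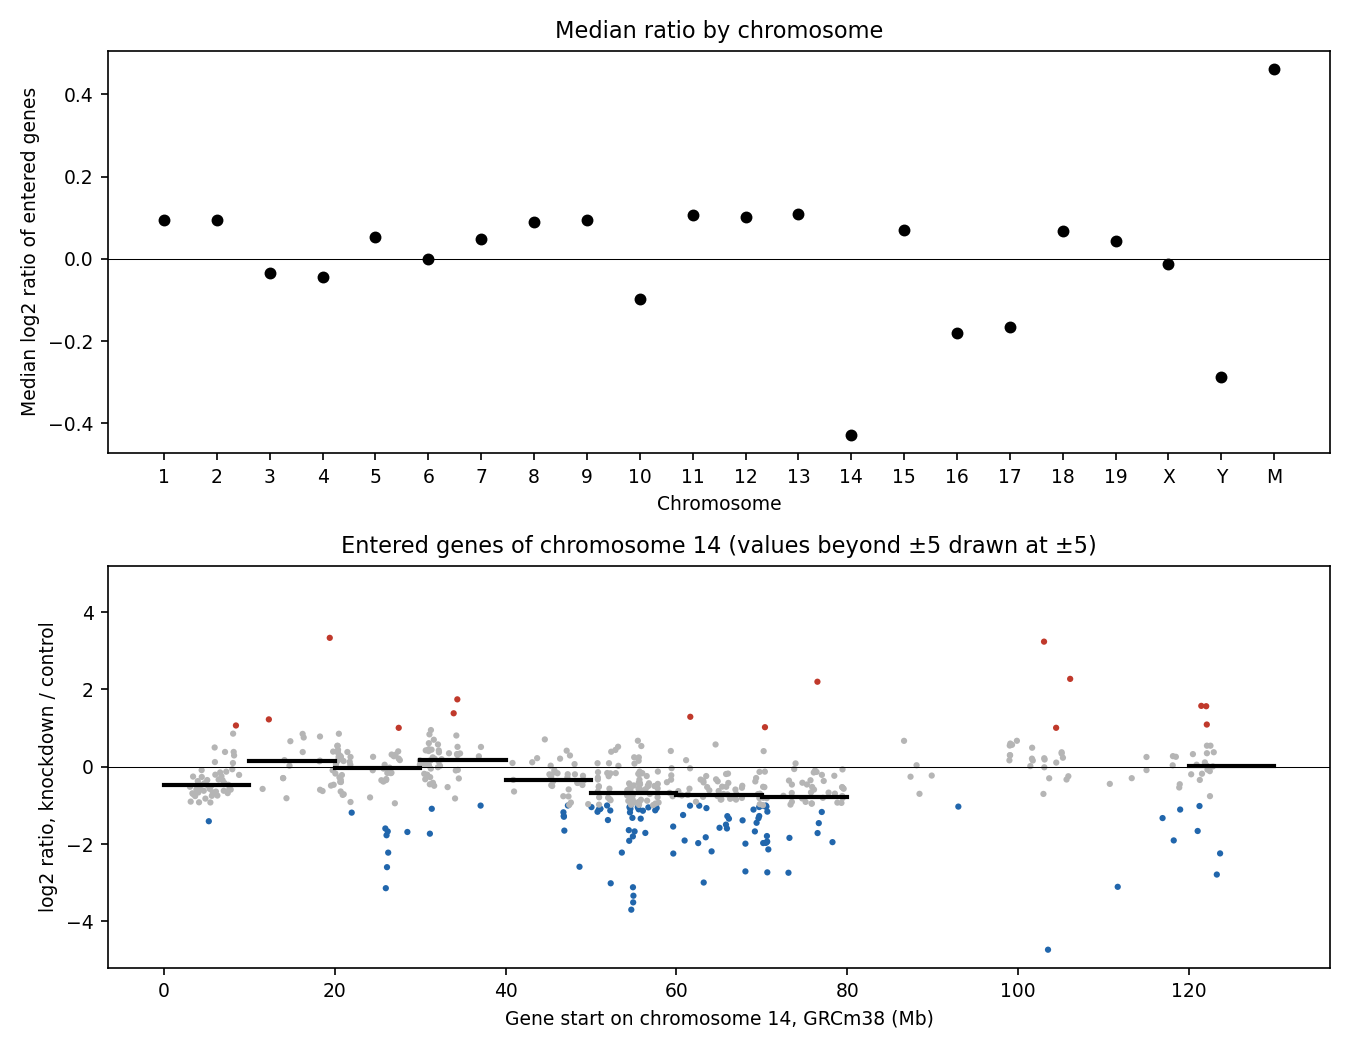
The upper panel gives the median log2 ratio of knockdown to control over the entered genes of each chromosome, and the lower panel each entered gene of chromosome 14 by its start in GRCm38 (red called higher, blue called lower, grey not called), with black bars for medians of 10 Mb windows of at least 20 genes. Chromosome 14 has the lowest median at -0.43, and its windows between 50 and 80 Mb lie between -0.78 and -0.69.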

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

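Chromosome 14 left out, nuclear protein-coding genes alone and centring by GC content were chosen after seeing the data. Calls near 2-fold depend on the fold and on the filter. The 742 higher and 1503 lower genes became 330 and 728 at 5 CPM, which tests fewer genes, 1817 and 2598 at 1.5-fold, and 152 and 389 at 4-fold. Under the other 10 settings both counts stayed within 1.5 times. Depth limits genes at 1 to 3 counts, such as Cer1 and Lhx1, to wide intervals. Without replicates no setting bears on the spread between clones.

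Of 310 list percentiles under the alternatives, 293 kept their side. With shared genes left out, pluripotency lay at 92.385, trophectoderm at 18.985, WNT at 6.52, imprinted genes at 8.76 and FGF-ERK at 0.45. At 5 CPM WNT lay at 1.355, p53 targets at 0.92, and imprinted genes changed direction (98.47, median 0.24). Without chromosome 14, pluripotency lay at 98.535 and p53 targets at 0.79. The p53 list lay at 0.85 when centred by expression level and 0.89 by gene length. Centring by GC content put it at 0.32, glycolysis at 99.87 and mitochondrially encoded genes at 97.935. With nuclear protein-coding genes alone WNT lay at 2.09, and with no filter HOX genes lay at 0.06. Leaving out shared genes changes both the size and the membership of a list, and the cause of these shifts was not tested.

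Of 240 chromosome percentiles, 223 kept their side, and chromosomes 10, 14, 16 and 17 did so under every setting run on them. With no filter, chromosome 2 lay at 93.44, 3 at 1.15, 5 at 99.76, 7 at 99.61 and 15 at 99.56. At 5 CPM, 12 lay at 95.5, 15 at 99.68, 18 at 99.02 and Y at 0.97. With nuclear protein-coding genes alone, 1 lay at 98.32, 12 at 94.9 and 15 at 99.66. Centred by GC content, 1 lay at 83.67, 7 at 100, 12 at 95.68, 15 at 99.99 and X at 0. The cause was not tested.

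For the 100 named genes, 824 values under other settings kept the call of a called gene or left an uncalled gene within its counting interval, 43 moved an uncalled gene outside it without a call, 2 gained a call (both Lifr) and 6 lost one (Cdkn2a under 3 settings, Ndrg1, Hoxb2 and Hoxc9). None changed direction among called genes.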

Other observations

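Tests on gene groups chosen after the first results were seen are those of the NF-kB, meiotic, Platr and macrophage groups, the chromosome 14 windows and the feeder tests. The expectation for the macrophage group was written before its median was seen, but after the values of Marco and Mrc1 were. Those for the feeder and chromosome 14 tests, with their bounds, were written after the first results were seen. The first 3 groups were drawn up because single members, among them Lcn2, Nos2, Acod1, Saa3, Cxcl1, Cxcl5, Stag3, Smc1b, Meioc, Tex11, Hormad1, Platr15 and Platr26, had been seen to be high, so only their counts are given and no percentile. Of 22 entered NF-kB and acute phase genes, 10 were higher, none was lower and 12 were not called. Cxcl1, a neutrophil chemokine, was 6.92-fold higher (5.02 to 9.75), Cxcl5 8.76-fold (4.93 to 16.9), Saa3 5.90-fold (3.40 to 11.0) and Il1b 11.0-fold (3.46 to 55.8, from 35 against 3 counts). The feedback inhibitor genes Nfkbia (log2 ratio 0.50) and Tnfaip3 (0.01) were not called. None of these genes is on a list fixed earlier.

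Of 19 entered meiotic chromosome genes, 8 were higher, 1 was lower and 10 were not called, and 3 of the 23 listed are on the earlier lists. The meiotic cohesin genes Stag3 and Smc1b were 5.50-fold (5.13 to 5.89) and 4.64-fold (4.12 to 5.24) higher, with 5593 against 958 and 1623 against 329 counts. Meioc was 4.51-fold higher (4.05 to 5.05), Stra8, the gene that retinoic acid induces at meiotic entry, 11.9-fold (4.82 to 37.8, from 63 against 5 counts), and Sycp3 was lower (log2 ratio -1.60). Noncoding transcripts named Platr for their association with pluripotency had 5 of 23 higher, 1 lower and 17 not called. Platr15 was 6.76-fold (4.54 to 10.4) and Platr26 6.33-fold (4.14 to 10.1) higher. The predicted genes Gm10800 (5965 against 608 counts) and Gm21738 (760 against 71) were also higher, named after their values were seen. They have near-identical copies, so where their reads come from is uncertain.

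The interferon genes were higher in a culture that held feeder cells, so another cell type was weighed first. A larger share of macrophages in the knockdown library should raise macrophage markers, but the 16 entered markers had a median log2 ratio of -1.17, with 10 lower and none higher. Their abundant members Cd68 (348 against 281 counts) and Laptm5 (316 against 298) were not called and Lyz2 (272 against 539) was lower. Adgre1 was 1.77-fold apart on the higher side (1.21 to 2.63, 81 against 43 counts). None of the 22 listed genes is on the earlier lists. The list held Mrc1 (19 against 190 counts) but not Marco (135 against 0), which was among the highest genes. Both values had been seen before the expectation was written. The low median therefore speaks only for macrophages that carry the listed markers, and a larger share of other macrophages, such as cells with Marco, stays open. A larger share of feeder fibroblasts is argued against by the median of -1.28 of their markers. A response within the stem cells or the feeders, to linc1557 loss or to this particular hairpin, may remain. The control cells carried a hairpin too, so a response shared by both would not by itself set the libraries apart. With 1 library per group, these and a difference between the picked clones are untested.

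Fibroblast markers were lower together with genes of the streak and endoderm, and fewer feeders in the knockdown library may account for part of this. Feeder loss alone should lower markers of fibroblasts by 1 common ratio. The log2 ratios of 12 such markers, all from the earlier list, had an SD of 0.79, against 0.13 from counting error. They ran from -2.44 for Col6a3 to 0.26 for Dcn. The spread between cultures is unknown with 1 library per group, so no SD could have counted against feeder loss as the only cause here. Stem cells can also supply some of these markers, and feeder loss as the only cause stays open. The 28 entered genes of the streak and endoderm lists had a median of -1.48, above that of Timp3 (-2.66), the lowest of the 30 fibroblast markers, though 9 had counting intervals wholly below Timp3's, so for the set feeder loss and a lower expression in the stem cells cannot be told apart with no spread between cultures to set this against (2 earlier bounds, on the genes called lower alone, were dropped after their values were seen). A smaller fraction of spontaneously differentiating cells in the knockdown culture is another candidate explanation, which was not tested.

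The low ratios on chromosome 14 were uneven along its length, since of 236 windows of 10 Mb, 3 had a median at or below -0.5, all from 50 to 80 Mb of chromosome 14, and none reached 0.5. The 251 genes there had a median of -0.73, the windows from 0 to 10 Mb (-0.47) and 40 to 50 Mb (-0.35) were low as well, and the other 4 windows of the chromosome lay between -0.04 and 0.17. Centring by GC content, length or level left the median at -0.74 or below, so these trends are not the whole cause, and a lower DNA copy number in the knockdown cells is a candidate explanation. When windows were chosen on every other gene, 4 and then 3 windows of chromosome 14 were taken (and 1 elsewhere in the second round). Of their 150 and 125 genes left out of the choice, 90% and 92.8% lay below the genome-wide median. The former was exactly at the bound, which had been set after the pattern was seen. The upper quartiles of these genes were -0.35 and -0.41, which argues against regulation of a few genes. The median of the region lay between the log2 ratios of 2 against 3 copies (-0.58) and 1 against 2 (-1), but DNA was not measured and regional regulation stays open.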
